A study of Mus musculus with 12 samples.

How the data were processed

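RNA was measured in 12 libraries of wild-type mouse trophoblast stem cells. Per the labels, cells were incubated with shRNA vectors and the reagent jetPRIME for 4 hours, cultured for another 44 hours in fresh medium and sorted by mCherry fluorescence. The 4 groups of 3 libraries were Cdx2 shRNA mCherry-positive, scrambled shRNA mCherry-positive, scrambled shRNA mCherry-negative and untransfected cells. Libraries were made with a stranded polyadenylated RNA kit and sequenced as single-end reads of 76 bases. Groups and replicate numbers were taken from the sample titles. A single label described the Cdx2 shRNA, and its sequence and the number of hairpins are not given in the sources used here.

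Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.9.1, aligned them to mm10 with STAR 2.5.2a and quantified genes with RSEM 1.3.0; their notes also name DESeq2 1.12.3. The deposited table held an RSEM expected count, which divides reads shared between genes by estimation, and the authors' TPM (transcripts per M) value for each of 24454 genes and each library. The gene annotation the authors used, and whether counting used the strand, are not given in the sources used here. Coordinates were therefore looked up by gene symbol in GENCODE M21, where 23534 of the symbols were found and 44 were at more than 1 place; Cyr61 and Ctgf were among those not found.

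Deposited expected counts, 3.4% of which were not whole numbers, were rounded and analysed with edgeR 4.0.16 in R 4.3.3. The low-count filter filterByExpr, given the 4 groups, kept 12490 genes. After TMM normalization the 12 libraries were fitted together with 1 coefficient per group by glmQLFit, and each of 6 contrasts was tested with glmQLFTest. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. The count of genes called in the same direction against all 3 control groups came from the same fit. CPM values are scaled with the TMM factors, and log2 values for components and lists used a prior count of 2. Standard errors are the absolute log2 fold change divided by the square root of its F statistic.

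Comparisons, tests, gene lists, the rule for naming genes and the settings named below as fixed beforehand were set before the data were examined. Always named were Cdx2, Tfap2c, Eomes, Elf5, Esrrb, Hand1, Prl3d1, Tpbpa and Gcm1, where measured. Named in addition were the 12 largest rises and 12 largest falls of knockdown against scrambled positive cells, and 5 and 5 of each other comparison, among called genes with a mean of at least 5 CPM and no overlap between groups. Up to 4 called members of each list were named in the main comparison and up to 2 in the others. Genes named outside this rule were chosen after their values were seen and stand in the closing section.

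The 22 lists held 363 entries. They were trophoblast stem cell maintenance, trophoblast giant cell, spongiotrophoblast and glycogen cell, syncytiotrophoblast and labyrinth, AP-2, GATA and other trophoblast transcription factors, mitosis, DNA replication, p53 targets, interferon response, unfolded protein and integrated stress response, immediate early, FGF and ERK feedback, BMP and TGF-beta feedback, cholesterol synthesis, glycolysis and hypoxia, epithelial junctions and keratins, mesenchymal transition, steroid synthesis, embryonic fibroblast, embryonic stem cell, extraembryonic endoderm and mitochondrially encoded genes. The mitochondrially encoded list had no gene in the deposited table, which left 21 lists with a measured gene. Each was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Members were also counted with p adjusted over the list alone. Across 126 list tests, 27 were called with the preset and 0 with an estimated correlation.

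Whether replicate numbers pair libraries between groups was checked by correlating deviations of log2 CPM from the group means. Among control groups every pair with the same number had a correlation over 0.1: 0.38, 0.55 and 0.46 for scrambled positive and negative, 0.36, 0.47 and 0.18 for scrambled positive and untransfected, and 0.42, 0.59 and 0.24 for scrambled negative and untransfected libraries. The result with the replicate number as a block therefore stands beside the unblocked result of these contrasts.

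The method was tested on simulated negative binomial data with each gene's mean over all 12 libraries and its fitted dispersion. Known changes were added to the knockdown group for genes with a mean of at least 5 CPM. Of genes changed 1.5-fold, 2-fold and 4-fold, 28.4%, 85.1% and 100% were recovered, and 5 of 147 calls were false. Recovery of genes at lower levels was not tested. Genes were drawn independently, whereas 55.2% of the real within-group variance lay on its first component. Recovery and the share of false calls can therefore differ in the real data. The libraries held 22.1 to 38.3 M counts, with a count in 14329 to 14981 genes.

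Settings also run, as fixed beforehand, were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of only the 2 groups compared, a replicate block, leaving out each library, and, for lists, camera with an estimated correlation and the rotation test fry. Settings chosen after seeing the data were a fit without knockdown 1, scrambled positive 2 and scrambled negative 2, removal of each library's trends with GC content and transcript length (loess, span 0.3), 1 surrogate variable from sva 3.50.0, limma on log2 of TPM plus 1, and a block over the 9 control libraries. Group labels were also rearranged in all 10 splits of the 6 libraries of a comparison and, for the count shared by all 3 knockdown contrasts, in 100 groupings of the 12 libraries. Overlaps were set beside 20 simulations of unchanged groups with the same shared libraries. No column of per-sample values was left unused.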

Results

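Polyadenylated RNA was sequenced from mouse trophoblast stem cells, the self-renewing precursors of the placental trophoblast, kept in medium conditioned by embryonic fibroblasts. Cells were transfected with an shRNA vector that also carried mCherry and were sorted 48 hours later. The 12 libraries fell into 4 groups of 3, called independent biological replicates by the submitters. These were mCherry-positive cells that had received the Cdx2 shRNA (knockdown), mCherry-positive cells that had received a scrambled shRNA (scrambled positive), mCherry-negative cells of the scrambled transfection (scrambled negative), and sorted untransfected cells. Total expected counts per library lay between 22.1 and 38.3 M (mega). They were 24.9, 38.3 and 36.8 M for the knockdown and 31.6, 22.1 and 34.8 M for scrambled positive cells. For scrambled negative cells they were 37.9, 27.8 and 36.4 M, and they were 29.9, 25.8 and 28.4 M for untransfected cells. Of 24454 genes in the table, 12490 had enough counts to be tested. Levels are counts per M counted (CPM) after TMM scaling, coordinates are GRCm38 (mm10), and an effect is a log2 fold change with its standard error (SE).

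Cdx2, the homeobox transcription factor targeted by the shRNA (chromosome 5, 147300805 to 147307270, minus strand), was measured at 90.3, 94.0 and 91.9 CPM in the knockdown libraries. It lay at 179.5, 206.5 and 209.6 CPM in scrambled positive, at 217.4, 272.5 and 228.7 CPM in scrambled negative and at 191.6, 235.1 and 235.2 CPM in untransfected cells. The knockdown libraries were thus below every control library, at 0.464 times the scrambled positive level. Cdx2 fell against every control group, with a log2 change of -1.11 against scrambled positive (SE 0.11, adjusted p = 0.00036), -1.26 against untransfected (SE 0.12, adjusted p = 8.8e-05) and -1.38 against scrambled negative cells (SE 0.12, adjusted p = 6.8e-05). Between control groups its log2 difference was -0.27 (scrambled positive against negative, adjusted p = 0.36), -0.15 (scrambled positive against untransfected, 0.66) and 0.12 (scrambled negative against untransfected, 0.94), and none of these was called. An exact test of 3 libraries against 3 cannot give a p below 0.10, so all p-values rest on spreads shared across genes.

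**Figure D1:**
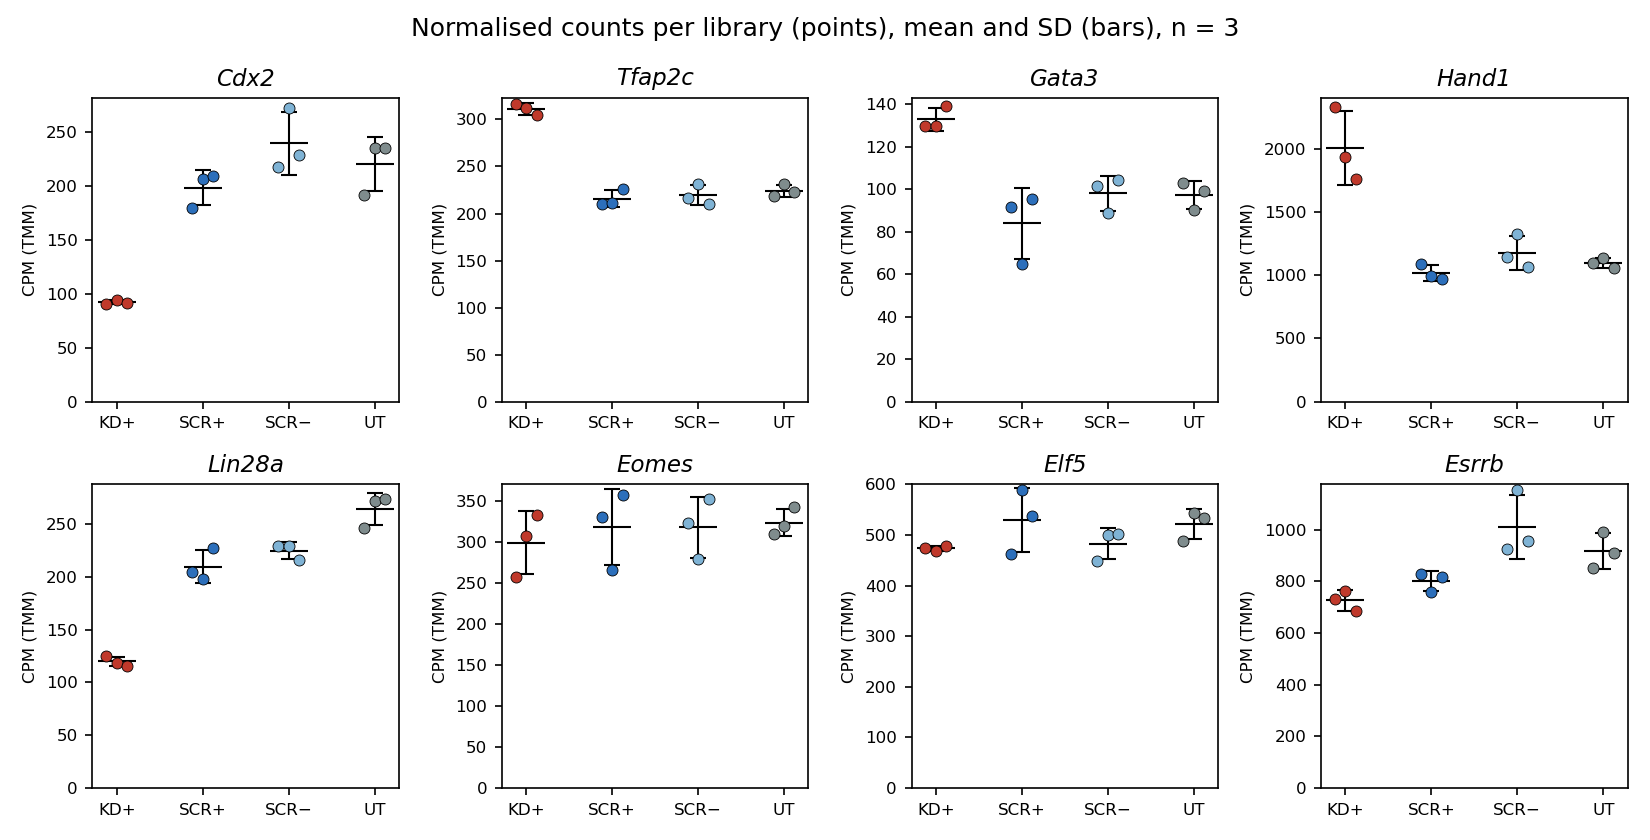
CPM (vertical axes, from 0) of 8 genes in each of the 12 libraries (points) for knockdown (KD+), scrambled positive (SCR+), scrambled negative (SCR−) and untransfected (UT) cells, with mean and SD as bars. Cdx2 and Lin28a were lower and Tfap2c and Hand1 higher in the 3 knockdown libraries than in every control library, while Eomes and Elf5 overlapped between knockdown and scrambled positive cells.

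The knockdown libraries separated from the controls along the second principal component (22% of the variance). They had scores of -27.6, -25.6 and -28.5, and the control libraries scores from 0.3 to 20.5. Among controls the scrambled positive libraries (5.2, 0.3 and 0.8) lay below the others (9.9 to 20.5), so this axis did not follow the Cdx2 shRNA alone. The component with the largest variance (37.1%) separated libraries within groups. Scrambled positive 2 (-42.4 against 7.2 and 9.9), scrambled negative 2 (-37.2 against 13.6 and 14.5) and, less far, untransfected 2 (-5.5 against 25.5 and 17.2) lay apart from the other libraries of their groups. The knockdown libraries were spread evenly (-21.5, -0.5 and 19.2). Rn45s, the ribosomal RNA precursor, took 2.71% of the counts in scrambled negative 2 and 2.49% in untransfected 2 against 5.45% to 7.51% in the other 10 libraries. Ribosomal protein genes took 13.48% of the counts in scrambled positive 2 and 10.71% in knockdown 1. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 10.48 or more), and each was counted as 1 replicate, as labelled.

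**Figure D2:**
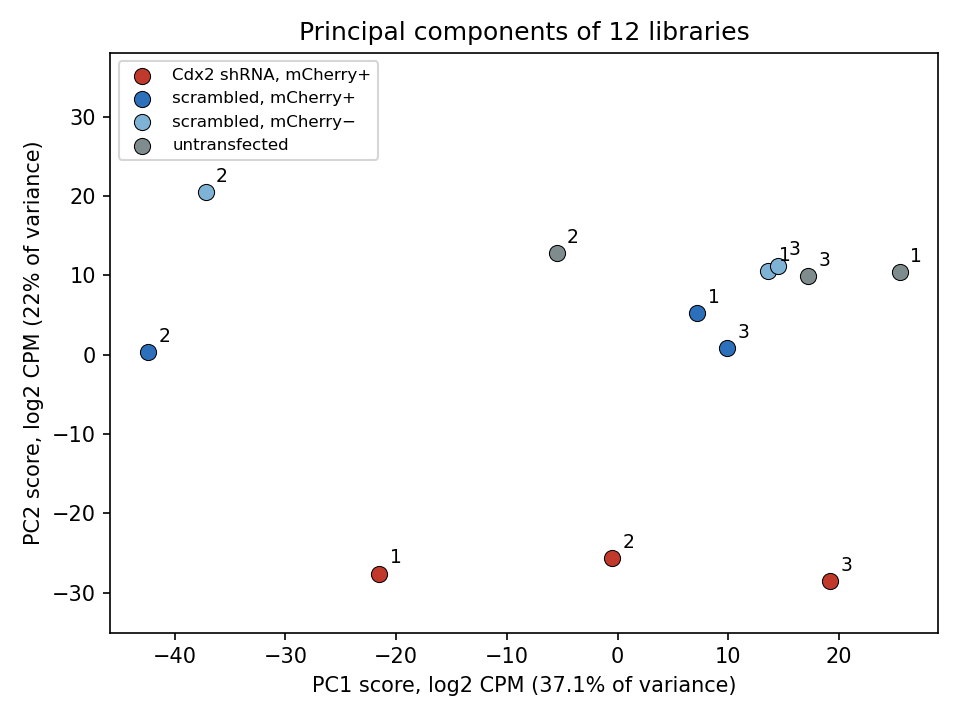
Scores of the 12 libraries on the principal components of log2 CPM over the tested genes, with PC1 (37.1% of the variance) on the horizontal and PC2 (22%) on the vertical axis; colours give the group and numbers the replicate. The 3 knockdown libraries have PC2 scores between -28.5 and -25.6, below all control libraries.

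The comparison of knockdown with scrambled positive cells asked what the Cdx2 shRNA changed among transfected, sorted cells. Tfap2c, which encodes the trophoblast transcription factor AP-2 gamma named in the study's title (chromosome 2, 172549593 to 172558622), rose from 216 ± 8.87 to 311 ± 6.13 CPM (SD, n = 3; log2 change 0.53, SE 0.07, adjusted p = 0.0020). Hand1, a transcription factor required for giant cell formation (chromosome 11, 57828705 to 57832818), rose from 1020 ± 63.1 to 2010 ± 293 CPM (0.99, SE 0.12, adjusted p = 0.00085). Lin28a, an RNA-binding inhibitor of let-7 maturation expressed in stem cells (chromosome 4, 134003330 to 134018841), fell from 210 ± 15.3 to 120 ± 4.72 CPM (-0.81, SE 0.08, adjusted p = 0.00036). Eomes, Elf5 and Esrrb, core transcription factors of trophoblast stem cells, were not called, at log2 values of -0.09 (SE 0.13, adjusted p = 0.83), -0.16 (SE 0.10, 0.48) and -0.14 (SE 0.11, 0.56).

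The rise with the largest log2 value among the named genes was that of Vgf, a secreted peptide precursor (chromosome 5, 137026392 to 137033351), from 3.91 ± 0.745 to 21.9 ± 1.66 CPM (2.48, SE 0.15, adjusted p = 1.3e-05). Prss22, a serine protease, rose by 2.04 (SE 0.21), and Cdh5, the VE-cadherin of endothelial junctions, by 1.81 (SE 0.28). Itgb3, the integrin beta 3 subunit, rose by 1.46 (SE 0.12) and Marcks, an actin-binding substrate of protein kinase C, by 1.48 (SE 0.27). Hsd17b2, an oxidising steroid dehydrogenase, rose by 1.49 (SE 0.20), A4galt, a glycosyltransferase, by 1.47 (SE 0.16) and Phactr1, an actin regulator, by 1.55 (SE 0.12). The 12 named rises also held Hist1h1c (linker histone H1, 1.45), Adssl1 (adenylosuccinate synthase, 1.44), Rgs16 (regulator of G protein signalling, 1.32) and Arhgef7 (exchange factor of Rho-family GTPases, 1.3), with adjusted p from 1.3e-05 to 0.0082 over all 12. Only Arhgef7 among these rises was also called between control groups in the fit without a replicate block. It was lower in scrambled positive than in scrambled negative cells (-0.71, adjusted p = 0.0066). In a fit of these 6 libraries alone Marcks was not called (adjusted p = 0.057).

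Serpinb1a, an inhibitor of serine proteases (chromosome 13, 32842092 to 32851185), fell from 11.5 ± 2.04 to 3.60 ± 0.426 CPM (-1.68, SE 0.14, adjusted p = 9.4e-05). Lhx6, a LIM homeobox transcription factor (chromosome 2, 36081953 to 36105408), fell from 18.5 ± 1.94 to 6.29 ± 0.685 CPM (-1.55, SE 0.12, adjusted p = 8.1e-05). Gata1, a transcription factor of blood cell lineages, fell from 15.3 ± 1.17 to 6.80 ± 1.19 CPM (-1.18, SE 0.14), and Upp1, the uridine phosphorylase, from 294 ± 81.9 to 119 ± 14.4 CPM (-1.3, SE 0.21). The other falls named by the rule were Fgd3 (-1.57), Tmem114 (-1.43), Acsbg1, an acyl-CoA synthetase (-1.36), Capn6 (-1.31), Klhdc8a (-1.31), Chac1, a glutathione-degrading enzyme (-1.13), Gm19705 (-1.11) and Cdx2 itself. Capn6 was also higher in scrambled positive than in scrambled negative cells (1.18, adjusted p = 0.038). In knockdown cells it was called against neither untransfected (-0.65, adjusted p = 0.068) nor scrambled negative cells (-0.13, adjusted p = 0.77). Counts of Serpinb1a, Serpinb9b, Hist1h1c and the prolactin family are less certain, because reads shared with close relatives are divided among them by estimation. The calls of Gm19705 and Chac1 were lost without any 1 of 4 libraries and without knockdown 2, with adjusted p up to 0.098 and 0.068 over all alternatives.

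In all, 655 of 12490 genes were called by the quasi-likelihood test of edgeR, 363 higher and 292 lower in knockdown cells. At least a 2-fold change was seen in 104 of the higher and 55 of the lower genes. All 655 separated the 3 knockdown from the 3 scrambled positive libraries without overlap, as did 23.0% of all tested genes, where chance gives 10%. By limma on TPM values 70.2% of the calls were higher, against 55.4% here. Without any 1 of the 6 libraries the count lay between 287 (without knockdown 2) and 595 (without scrambled positive 2), and a fit of these 6 libraries alone called 263, in which Ctgf and Col4a1, described below, were not called.

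Trophoblast lineage genes were compared as lists fixed before the data were examined. Of 11 measured trophoblast giant cell genes, 4 rose and none fell (5 rose adjusted over the list alone). These were Hand1, Adm, the vasodilator peptide adrenomedullin (2.00, SE 0.46, adjusted p = 0.027), Serpinb9b, a placental protease inhibitor (1.38, SE 0.26, adjusted p = 0.010), and Podxl, a sialomucin (0.44, SE 0.11, adjusted p = 0.035). Podxl was called against neither untransfected (0.28, adjusted p = 0.17) nor scrambled negative cells (0.265, adjusted p = 0.17). The list's median log2 change was 0.57. It was called by camera (adjusted p = 0.0014) and fry (adjusted p = 0.0075), but not by camera with an estimated correlation between genes (adjusted p = 0.13). The median member was Prl3d2, which was not called (0.57, SE 1.05, adjusted p = 0.86). Only 11 of the 20 listed genes had enough counts to be tested, and Prl4a1, Prl3b1, Prl2b1, Ctsq and Ctsj had 0 counts. A rise across giant cell genes beyond the called members is therefore not shown. Prl3d1, the placental lactogen made by giant cells, was detected at 1.99 ± 1.62 CPM in knockdown and 1.38 ± 0.655 CPM in scrambled positive cells and was not called (0.43, SE 0.67, adjusted p = 0.84). The call of Adm was lost on leaving out any 1 of 5 of the 6 libraries (all but scrambled positive 2), that of Podxl any 1 of 4 (the knockdown libraries and scrambled positive 3) and that of Serpinb9b scrambled positive 3, with adjusted p up to 0.11, 0.16 and 0.053 over all alternatives.

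Among 20 stem cell maintenance genes, Lin28a and Ddah1, an enzyme that degrades asymmetric dimethylarginine (-0.45, SE 0.11, adjusted p = 0.032), fell, Bmp4 rose (0.45, SE 0.10, adjusted p = 0.029) and 17 were not called. Counts adjusted over the list alone were the same, 1 higher and 2 lower, and the list as a whole was not called (median -0.03, adjusted p = 0.71). Of 12 AP-2, GATA and other trophoblast transcription factors, Tfap2c and Gata3, a zinc-finger factor of the trophectoderm (84.0 ± 16.7 to 133 ± 5.50 CPM; 0.66, SE 0.13, adjusted p = 0.015), rose and 10 were not called (4 rose adjusted over the list alone; list adjusted p = 0.12). Gata3 was not called against untransfected (0.45, adjusted p = 0.0756) or scrambled negative cells (0.44, adjusted p = 0.0718). Of 11 spongiotrophoblast and glycogen cell genes only Cdkn1c, an inhibitor of cyclin-dependent kinases, was called, and it fell (-0.47, SE 0.11, adjusted p = 0.024; 1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.60). Tpbpa, the classical marker of that layer, had 0 counts in all 12 libraries. Of 12 syncytiotrophoblast and labyrinth genes only Cebpa, a leucine zipper transcription factor, was called, and it fell (-0.84, SE 0.18, adjusted p = 0.017; 1 rose and 3 fell adjusted over the list alone; list adjusted p = 0.21). Fry called the syncytiotrophoblast and labyrinth list (adjusted p = 0.0091). Gcm1, a regulator of syncytiotrophoblast, had 26 counts over all libraries and was not tested. Without knockdown 2 or knockdown 3 the call of Gata3 was lost (adjusted p up to 0.084 over all alternatives), and the calls of Ddah1, Bmp4, Cdkn1c and Cebpa were each lost without any 1 of 3 to 5 libraries. Bmp4 was called against neither untransfected (0.17, adjusted p = 0.41) nor scrambled negative cells (0.17, adjusted p = 0.385). The same held for Cdkn1c (-0.325, adjusted p = 0.0997, and -0.31, adjusted p = 0.11).

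Epithelial genes were called lower as a list by camera against scrambled positive cells. Of 18 measured genes of junctions and keratins, 3 fell and none rose (1 rose and 8 fell adjusted over the list alone). They were Cldn4, a tight junction claudin (857 ± 50.6 to 540 ± 87.9 CPM; -0.67, SE 0.14, adjusted p = 0.019), Tjp3, a junctional scaffold (-0.51, SE 0.13, adjusted p = 0.040), and Esrp1, a splicing regulator of epithelial cells (-0.38, SE 0.08, adjusted p = 0.025). Camera called the list down (median -0.30, adjusted p = 0.0097), and fry also called it (adjusted p = 0.00058). Camera with an estimated correlation (-0.03) did not call the list (adjusted p = 0.13). Camera did not call it against untransfected (median -0.19, adjusted p = 0.14, but 0.017 by the rotation test fry; 1 rose and 1 fell) or scrambled negative cells (median -0.09, adjusted p = 0.35; 1 rose and 2 fell). In scrambled positive cells its median was 0.14 against scrambled negative (adjusted p = 0.069) and 0.11 against untransfected cells (adjusted p = 0.082), not called by camera but called by fry (adjusted p = 0.018 and 0.013). Of 17 glycolysis and hypoxia genes Vegfa, the vascular growth factor, rose (53.8 ± 8.41 to 101 ± 7.02 CPM; 0.91, SE 0.14, adjusted p = 0.0037) and Ankrd37, a hypoxia-induced gene, fell (-0.55, SE 0.13, adjusted p = 0.026), with 1 higher and 4 lower adjusted over the list alone. That list was called down (median -0.28, adjusted p = 0.023, and 0.014 by fry), not with an estimated correlation (adjusted p = 0.26) and not without knockdown 3. Of 15 cholesterol synthesis genes none was called (1 higher adjusted over the list alone), while the list was called up (median 0.15, adjusted p = 0.032, and 0.0061 by fry). It was not called with an estimated correlation (adjusted p = 0.13), nor without knockdown 2, knockdown 3 or scrambled positive 2. Camera did not call it against untransfected (median 0.07, adjusted p = 0.27) or scrambled negative cells (median 0.16, adjusted p = 0.26), but fry did (adjusted p = 0.034 and 0.011). The calls of Cldn4, Tjp3, Esrp1 and Ankrd37 were each lost without any 1 of 3 to 5 libraries, with adjusted p up to 0.088, 0.15, 0.42 and 0.13 over all alternatives. Tjp3 was called against neither untransfected (-0.22, adjusted p = 0.40) nor scrambled negative cells (0.10, adjusted p = 0.725).

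Immediate early genes moved both ways, as 6 of 19 rose and 3 fell (7 and 3 adjusted over the list alone; list adjusted p = 0.14). Cyr61 and Ctgf, which encode secreted matricellular proteins, fell, with changes of -1.08 (SE 0.12, adjusted p = 0.00066) and -0.80 (SE 0.14, adjusted p = 0.0063). Ier3 also fell (-0.71, SE 0.12, adjusted p = 0.0059), and Fosb, a subunit of AP-1, rose from 1.42 ± 0.367 to 2.96 ± 0.613 CPM (1.06, SE 0.27, adjusted p = 0.045). Ctgf was called against neither untransfected (-0.235, adjusted p = 0.415) nor scrambled negative cells (-0.236, adjusted p = 0.37). Of 12 feedback genes of FGF and ERK signalling, the pathway that keeps these cells proliferating, Spry1 (-0.69, SE 0.14), Spry4 (-0.54, SE 0.12) and the phosphatase gene Dusp6 (-0.59, SE 0.13) fell and none rose (2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.21). Of 16 unfolded protein and integrated stress genes, Chac1, Ppp1r15a, a phosphatase subunit that restores translation (-0.85, SE 0.11, adjusted p = 0.0012), and the transcription factor Atf4 (-0.44, SE 0.11, adjusted p = 0.043) fell. None rose (the same 0 and 3 adjusted over the list alone; list adjusted p = 0.20). Of 11 mesenchymal genes, Vim, the intermediate filament vimentin (0.95, SE 0.24, at 1.65 ± 0.278 CPM in knockdown cells), and Snai1, a repressor of E-cadherin (0.49, SE 0.12), rose. Fn1, fibronectin (320 ± 95.9 to 181 ± 17.9 CPM; -0.83, SE 0.18), fell (2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.24). Calls of Fosb, Vim, Snai1, Spry1, Spry4, Dusp6, Fn1 and Atf4 were lost without any 1 of at least 4 of the 6 libraries, and that of Chac1 without knockdown 2.

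None of 22 mitosis, 20 DNA replication or 19 p53 target genes was called, over all genes or adjusted over the list alone, and their medians were -0.10, -0.16 and -0.10 (list adjusted p = 0.17, 0.080 and 0.37). Of 13 interferon response genes only Stat1, the signal-transducing transcription factor, was called, and it rose (0.66, SE 0.12, adjusted p = 0.0067; 2 adjusted over the list alone; list adjusted p = 0.34). Of 9 BMP and TGF-beta feedback genes only Serpine1, the plasminogen activator inhibitor, was called, and it rose (0.48, SE 0.09, adjusted p = 0.011; 2 adjusted over the list alone; list adjusted p = 0.20); its call was lost without knockdown 1. Of 5 steroid synthesis genes only Hsd17b2 rose (1 rose and 1 fell adjusted over the list alone; median -0.03, mean 0.12, list adjusted p = 0.82). Markers of other cell types were followed too. Of 8 extraembryonic endoderm markers, the basement membrane genes Col4a1 (0.72, SE 0.13), Sparc (0.46, SE 0.11) and Lama1 (0.84, SE 0.19) rose (3 adjusted over the list alone; list adjusted p = 0.066). Fry called the endoderm list (adjusted p = 0.013). Gata6 stayed at or under 0.14 CPM and Sox17 at or under 0.04 CPM in every library. None of 7 embryonic stem cell markers was called, over all genes or adjusted over the list alone (median 0.01, mean -0.02, list adjusted p = 0.77). Of 4 fibroblast markers only Thy1 was called, and it fell, at 0.532 and 0.139 CPM (-2.00, SE 0.46, adjusted p = 0.028; the same 1 adjusted over the list alone; median 0.25, mean -0.26, list adjusted p = 0.79). Col1a1, an abundant fibroblast collagen, did not exceed 0.25 CPM in any library. Calls of Sparc, Lama1 and Thy1 were each lost without any 1 of 4 or 5 of the libraries. Lama1 was called against neither untransfected (0.21, adjusted p = 0.61) nor scrambled negative cells (0.10, adjusted p = 0.82). The same held for Thy1 (-1.23, adjusted p = 0.21, and -1.22, adjusted p = 0.17).

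**Figure D3:**
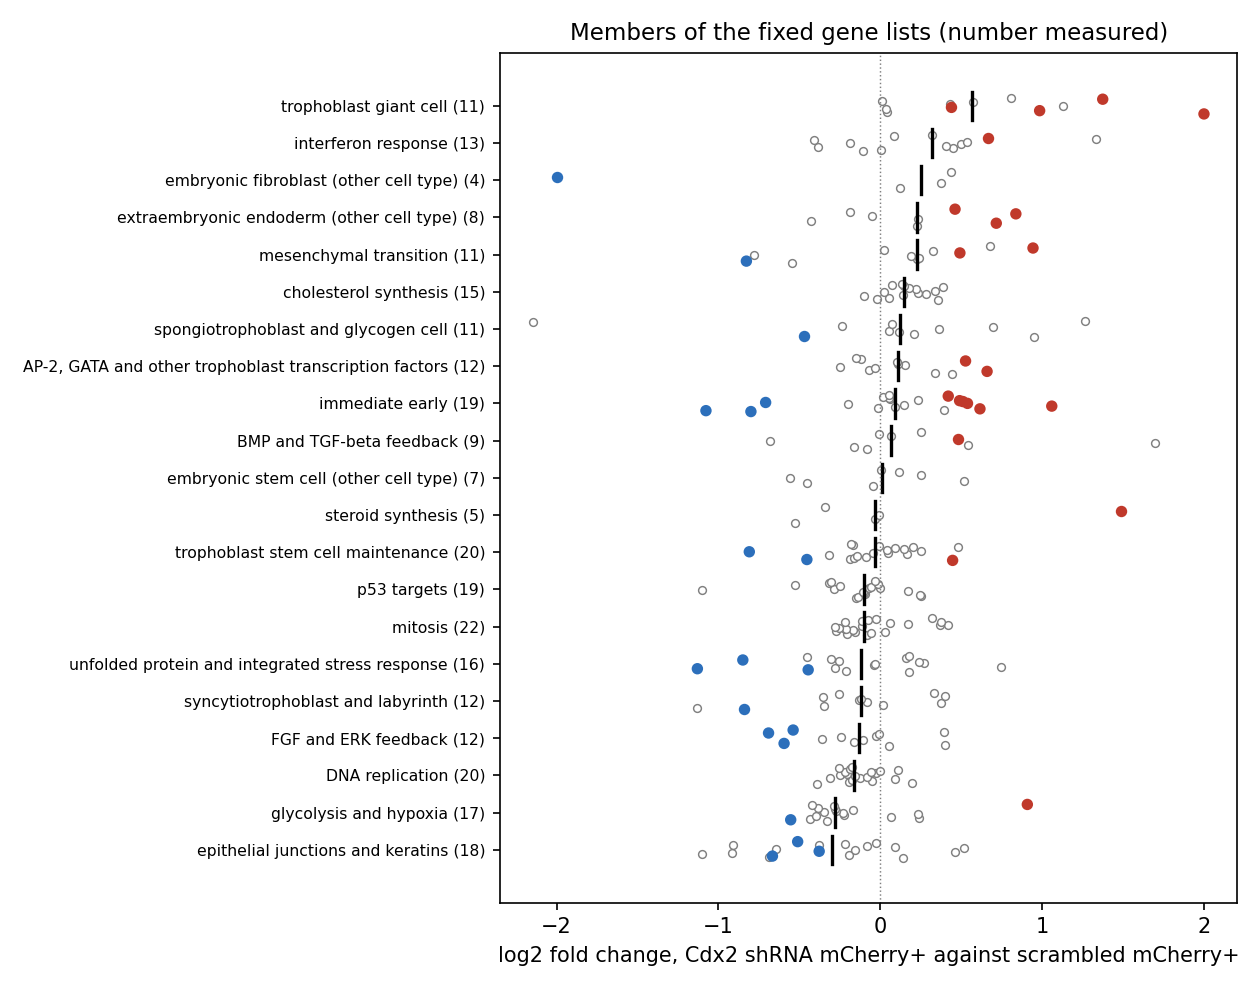
Log2 fold change (horizontal axis) of each measured member of 21 gene lists between knockdown and scrambled positive cells, with lists on the vertical axis and their number of measured members in brackets. Filled points passed the test over all genes, open points did not, and bars mark medians, from 0.57 for giant cell genes to -0.30 for epithelial genes.

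Against untransfected cells, a contrast that also holds transfection and vector effects, Tfap2c rose by 0.47 (SE 0.07, adjusted p = 0.0030) and Hand1 by 0.88 (SE 0.12, adjusted p = 0.0012). Vgf rose from 2.12 ± 0.234 to 21.9 ± 1.66 CPM (3.37, SE 0.16, adjusted p = 1.5e-06), and Cdh5 (2.46), Prss22 (2.25), Hist1h1c (2.10) and Tfpi, an inhibitor of the tissue factor pathway of coagulation (1.95, SE 0.18), also rose. Serpinb1a (-1.89, SE 0.14), Chac1 (-1.72, SE 0.21), Exoc3l (-1.50, SE 0.20) and Lhx6 (-1.36, SE 0.12) had, with Cdx2, the largest falls among called genes with a mean of at least 5 CPM. Eomes (-0.11), Elf5 (-0.14), Esrrb (-0.34) and Prl3d1 (0.32) were not called (adjusted p = 0.71, 0.51, 0.092 and 0.85). By limma on TPM the call of Tfap2c was lost (adjusted p = 0.071).

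Giant cell genes were called up against untransfected cells (median 0.81, adjusted p = 3.4e-05). Of 11 genes 5 were higher and none lower (6 adjusted over the list alone), among them Serpinb9b (2.00, SE 0.27) and Adm (1.69, SE 0.45). The list was not called with an estimated correlation (adjusted p = 0.16). Stem cell maintenance genes were called down (median -0.13, adjusted p = 0.0095; adjusted p = 0.40 with an estimated correlation). Of its 20 genes 5 were lower, led by Lin28a (-1.14, SE 0.09) and Duox2, an oxidase that makes hydrogen peroxide (-0.74, SE 0.16), and none higher (1 and 6 adjusted over the list alone). The FGF and ERK feedback list was called down (median -0.29, adjusted p = 0.0062; adjusted p = 0.36 with an estimated correlation). Spry1 (-0.88, SE 0.14), Spry4 (-0.82, SE 0.12) and 2 others of 12 were lower (5 adjusted over the list alone). Glycolysis and hypoxia genes were called down (median -0.31, adjusted p = 0.0062; adjusted p = 0.19 with an estimated correlation). Pdk1, a kinase of pyruvate dehydrogenase (-0.50, SE 0.11), and 1 other of 17 were lower while Vegfa rose (0.66, SE 0.14; 1 higher and 5 lower adjusted over the list alone). Interferon response genes were called up (median 0.32, adjusted p = 0.020; adjusted p = 0.19 with an estimated correlation). Of its 13 genes 3 were higher (5 adjusted over the list alone), including Oasl2 (1.82, SE 0.37) and the RNA sensor gene Ifih1 (1.40, SE 0.34). BMP and TGF-beta feedback genes were called up (median 0.12, adjusted p = 0.035; adjusted p = 0.19 with an estimated correlation). Id3, an inhibitor of basic helix-loop-helix factors (1.83, SE 0.23), and Serpine1 (1.13, SE 0.09) were the 2 higher of 9 (2 adjusted over the list alone). Camera called the stem cell, FGF and interferon lists the same way between scrambled positive and untransfected cells (medians -0.20, -0.17 and 0.14). Between knockdown and scrambled positive cells camera did not call them (adjusted p = 0.71, 0.21 and 0.34). As lists, their changes here can therefore not be assigned to the Cdx2 shRNA. Without knockdown 1 the calls of the stem cell and BMP lists were lost. Calls of Duox2, Pdk1, Vegfa and Oasl2 were each lost without any 1 of 2 to 5 libraries, with adjusted p up to 0.088, 0.11, 0.19 and 0.062 over all alternatives.

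Other members that passed the test against untransfected cells included Krt7, a keratin of trophoblast (0.94, SE 0.16), Cdkn1a, the cell cycle inhibitor p21 (0.92, SE 0.16), Plk2 (0.74, SE 0.10), Lgals3, galectin-3 (0.94, SE 0.19), Hsd17b2 (1.6, SE 0.20) and Vim (1.36, SE 0.25), all higher. Ccne1, cyclin E1 (-0.47, SE 0.12), Uhrf1, which maintains DNA methylation (-0.41, SE 0.11), Trib3 (-1.04, SE 0.25), Cebpa (-0.72, SE 0.18) and Cyr61 (-0.78, SE 0.12) were lower. Against scrambled positive cells Cdkn1a (-0.10, adjusted p = 0.83), Plk2 (-0.06, 0.86), Lgals3 (0.02, 0.98) and Krt7 (0.52, 0.097) were not called. Ccne1 (-0.39, adjusted p = 0.089), Uhrf1 (-0.17, 0.47) and Trib3 (-0.455, 0.42) were not called there either. In total 781 genes were called by edgeR, 456 higher (58.4%) and 325 lower, with 167 and 47 of them changed at least 2-fold. All 781 separated the libraries without overlap, as did 31.1% of all tested genes. By limma on TPM 47.8% of the calls were higher. Without any 1 library the count was between 352 (without untransfected 3) and 475 (without knockdown 1, and the same without knockdown 3), and the calls of Uhrf1, Ccne1, Trib3, Ifih1 and Adm were each lost without any 1 of at least 5 of the 6. The call of Cebpa was lost without any 1 of 4 libraries and that of Lgals3 without untransfected 3.

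Against scrambled negative cells, a contrast that also holds the mCherry gate, Tfap2c rose by 0.50 (SE 0.07, adjusted p = 0.0020), Hand1 by 0.77 (SE 0.12, adjusted p = 0.0028) and Vgf by 2.75 (SE 0.15, adjusted p = 8.8e-06). Cdh5 (2.16, SE 0.28), Tfpi (2.03, SE 0.18), Rhox9, an X-linked homeobox gene (2.01, SE 0.28), and Hist1h1c (1.94, SE 0.16) rose, while Exoc3l (-1.80, SE 0.20), Serpinb1a (-1.74, SE 0.14), Lhx6 (-1.58, SE 0.12) and Fgd3 (-1.42, SE 0.15) fell. Here Esrrb fell as well, from 1010 ± 123 to 726 ± 39.1 CPM (-0.48, SE 0.11, adjusted p = 0.019), a call lost without any 1 of the knockdown libraries. Eomes (-0.09, adjusted p = 0.78), Elf5 (-0.03, 0.92) and Prl3d1 (1.6, 0.23) were not called.

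Giant cell genes were called up against scrambled negative cells (median 0.80, adjusted p = 0.00062; adjusted p = 0.14 with an estimated correlation), and 3 of 11 were higher (5 adjusted over the list alone). FGF and ERK feedback genes were called down (median -0.33, adjusted p = 0.00046; adjusted p = 0.30 with an estimated correlation). Spry4 (143 ± 5.23 to 71.7 ± 1.79 CPM; -1, SE 0.12), Spry1 (-0.98, SE 0.14) and 1 other of 12 were lower (7 adjusted over the list alone). Glycolysis and hypoxia genes were called down (median -0.30, adjusted p = 0.00062; adjusted p = 0.14 with an estimated correlation). Slc2a1, a glucose transporter (-0.48, SE 0.12), and 1 other of 17 were lower and Vegfa (0.66, SE 0.14) was higher (1 and 7 adjusted over the list alone). Stem cell maintenance genes were called down (median -0.11, adjusted p = 0.031; adjusted p = 0.62 with an estimated correlation and 0.093 by fry). Of its genes 6 of 20 were lower, among them Duox2 (-0.95, SE 0.16) and Lin28a (-0.91, SE 0.08), and 1 was higher (1 and 6 adjusted over the list alone). DNA replication genes were called down (median -0.15, adjusted p = 0.031; adjusted p = 0.42 with an estimated correlation). Ccne1 (-0.66, SE 0.12) and Uhrf1 (-0.54, SE 0.11) were the 2 lower of 20 (1 higher and 3 lower adjusted over the list alone). Interferon response genes were called up (median 0.45, adjusted p = 0.0073; adjusted p = 0.14 with an estimated correlation). Of its genes 4 of 13 were higher (5 adjusted over the list alone), led by Oasl2 (2.14, SE 0.37) and Gbp2 (1.99, SE 0.46), which both stood under 2 CPM. The stem cell list was not called without knockdown 1, scrambled negative 1 or scrambled negative 3, and the DNA replication list not without knockdown 3 or scrambled negative 3. Camera called the stem cell, FGF and interferon lists the same way between scrambled positive and scrambled negative cells (medians -0.15, -0.25 and 0.22). It called none of them between knockdown and scrambled positive cells. As lists, their changes here can therefore not be assigned to the Cdx2 shRNA.

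Among other list members, Fn1 (422 ± 13.1 to 181 ± 17.9 CPM; -1.22, SE 0.18), Cyr61 (-0.97, SE 0.12), Ppp1r15a (-0.77, SE 0.11), Chac1 (-1.14, SE 0.21), Cebpa (-0.87, SE 0.18) and Cldn3 (-0.82, SE 0.19) were lower than in scrambled negative cells. Id3 (1.64, SE 0.22), Plk2 (0.83, SE 0.10), Serpine1 (0.61, SE 0.09), Krt7 (0.65, SE 0.16) and Cyp51, an enzyme of cholesterol synthesis (0.39, SE 0.09), were higher. Against scrambled positive cells Id3 (0.54, adjusted p = 0.19), Plk2 (-0.06, 0.86) and Krt7 (0.52, 0.097) were not called. Nor were Cyp51 (0.355, adjusted p = 0.051) and Cldn3 (-0.685, 0.067). In total 920 genes were called by edgeR, 496 higher (53.9%) and 424 lower, with 172 and 43 changed at least 2-fold. By limma on TPM 44.7% and by DESeq2 49.4% of the calls were higher. All 920 separated the libraries without overlap, as did 27.7% of all tested genes. Without any 1 library the count was between 401 (without knockdown 2) and 708 (without scrambled negative 2), and a fit of these 6 libraries alone called 349. Calls of Slc2a1, Gbp2, Vegfa, Krt7, Cyp51 and Cldn3 were each lost without any 1 of 3 to 5 libraries, and those of Uhrf1 and Cebpa without knockdown 3.

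Across the 3 contrasts, 377 genes were called against every control group in the same direction, 222 higher and 155 lower. Cdx2, Lin28a, Lhx6, Serpinb1a, Chac1, Cyr61 and Cebpa were among the lower ones. Tfap2c, Hand1, Vgf, Cdh5, Hist1h1c, Serpinb9b, Adm, Vegfa, Hsd17b2, Col4a1, Serpine1 and Fosb were among the higher. With scrambled positive and untransfected cells as controls 264 genes were higher and 171 lower in both, and with scrambled positive and scrambled negative cells 239 and 176. Independent lists of these sizes would share 13.3 and 7.6 genes, and 14.4 and 9.9 genes, and all 3 lists 0.78 genes in the same direction. In 20 simulations of unchanged groups with the same shared knockdown libraries the overlap was at most 0, 1 and, for all 3 contrasts, 0 genes. There 66.4% of genes had the same sign in a pair of contrasts. Few genes can be called where no group was changed. The simulated overlaps therefore cannot show how much of the real overlap comes from sharing the knockdown libraries. The knockdown libraries entered all 3 contrasts, so the 3 lists were not independent. No gene was called with opposite signs, and 182 of the 655 genes called against scrambled positive cells were called against neither other control. Without knockdown 1, 2 or 3 the count of 377 became 208, 171 and 221, and without scrambled positive 1, untransfected 1 or untransfected 3 it became 245, 242 and 217.

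The comparison of scrambled positive with scrambled negative cells, sorted after the scrambled transfection, gives the effect of carrying the vector and of the gate. Emp1, an epithelial membrane protein (19.9 ± 2.77 against 7.78 ± 2.00 CPM; 1.36, SE 0.21, adjusted p = 0.038), Nxf7, an X-linked gene of the RNA export factor family (1.32, SE 0.16, adjusted p = 0.0073), Capn6 (1.18, SE 0.19), Papss2, an enzyme of sulfate activation (0.96, SE 0.13), and Plk2, a stress-responsive kinase (0.89, SE 0.10), were higher in scrambled positive cells. St3gal1, a sialyltransferase (-0.87, SE 0.12), Nol4l (-0.83, SE 0.12), Arhgef7 (128 ± 2.58 to 78.1 ± 4.60 CPM; -0.71, SE 0.08, adjusted p = 0.0066), Mgat4b, a glycosyltransferase (-0.69, SE 0.11), and D17Wsu92e (-0.58, SE 0.09) were lower. Tfap2c (-0.02, adjusted p = 0.95), Hand1 (-0.22, 0.51), Eomes (0.00, 1), Elf5 (0.13, 0.66), Esrrb (-0.33, 0.24) and Prl3d1 (1.17, 0.58) were not called. In total 16 genes were called by edgeR, 11 higher and 5 lower, of which 5 rose at least 2-fold, and 1574 genes had an unadjusted p under 0.05. All 16 separated the libraries without overlap, as did 16% of all tested genes. With the replicate number as a block 31 genes were called (24 higher, 7 lower). Same-numbered libraries correlated at 0.38, 0.55 and 0.46, but the number is not known to pair them. With such a block over the 9 control libraries alone 121 were called (79 higher, 42 lower). Higher genes made up 68.8% of the calls, 33.3% of 6 calls by limma on TPM and 58.4% of 178 calls after a correction for GC content and length. Without any 1 library between 2 (without scrambled positive 3) and 13 (without scrambled negative 2) genes were called, and only Arhgef7 of the 10 genes named here stayed called each time, while a fit of these 6 libraries alone called 0.

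Camera with the preset correlation called 5 lists between scrambled positive and negative cells, none of them with an estimated correlation and none with a called member. Fry did not call the FGF and ERK feedback, stem cell and immediate early lists among them (adjusted p = 0.069, 0.32 and 0.12). FGF and ERK feedback genes were called down in scrambled positive cells (median -0.25, adjusted p = 0.00015; adjusted p = 0.22 with an estimated correlation), with none of 12 called (3 lower adjusted over the list alone). Stem cell maintenance genes were called down (median -0.15, adjusted p = 0.0075; adjusted p = 0.51 with an estimated correlation), as were immediate early (median -0.14, adjusted p = 0.014; 0.22 with an estimated correlation) and mesenchymal genes (median -0.28, adjusted p = 0.014; 0.19 with an estimated correlation). None of their 20, 19 and 11 members was called (1 higher and 3 lower, 1 higher and 3 lower, and 0 adjusted over the list alone). Interferon response genes were called up (median 0.22, adjusted p = 0.012; adjusted p = 0.19 with an estimated correlation), with none of 13 called (2 higher adjusted over the list alone). Without scrambled positive 2, which stood apart from the other libraries of its group, the stem cell, interferon, immediate early and mesenchymal lists were not called, nor the interferon and immediate early lists without scrambled positive 3, nor the immediate early and mesenchymal lists without scrambled negative 2.

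Against untransfected cells, scrambled positive cells show the joint effect of transfection with the control vector and of the mCherry-positive gate, as the gate of the untransfected cells is not given. Emp1 (19.9 ± 2.77 against 7.09 ± 1.09 CPM; 1.49, SE 0.21, adjusted p = 0.026), Sbsn, suprabasin (1.09, SE 0.15), Cdkn1a (12.7 ± 0.901 to 25.7 ± 1.47 CPM; 1.02, SE 0.16, adjusted p = 0.036), Papss2 (1.02, SE 0.13), Nxf7 (0.99, SE 0.15), Plk2 (0.80, SE 0.10) and Serpine1 (0.65, SE 0.09) were higher. Arhgef7 (-0.70, SE 0.08, adjusted p = 0.0078) and Nol4l (-0.78, SE 0.12, adjusted p = 0.040) were lower. Tfap2c (-0.06, adjusted p = 0.80), Hand1 (-0.11, 0.76), Eomes (-0.02, 0.96), Elf5 (0.02, 0.94), Esrrb (-0.19, 0.59) and Prl3d1 (-0.11, 0.96) were not called. In total 15 genes were called by edgeR, 13 higher and 2 lower, of which 8 rose at least 2-fold, and 1186 had an unadjusted p under 0.05. All 15 separated the libraries without overlap, as did 17.4% of all tested genes. With the replicate number as a block 38 genes were called (25 higher, 13 lower). Same-numbered libraries correlated at 0.36, 0.47 and 0.18, and again the number is not known to pair them. With such a block over the 9 control libraries alone 736 were called, and most were lower (216 higher, 520 lower). Higher genes made up 86.7% of the calls, 66.7% of 3 calls by limma on TPM and 57.5% of 106 calls after a correction for GC content and length. Of the 24 genes called in either contrast of scrambled positive with another control, 7 were called in both, and 11 were among the 655 genes called between knockdown and scrambled positive cells. Without any 1 library between 1 (without scrambled positive 3, and the same without untransfected 1) and 8 (without scrambled positive 2) genes were called, none of the 9 genes named here stayed called each time, and a fit of these 6 libraries alone called 0.

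Stem cell maintenance genes (median -0.20, adjusted p = 0.00044; adjusted p = 0.33 with an estimated correlation) and FGF and ERK feedback genes (median -0.17, adjusted p = 0.011; adjusted p = 0.33 with an estimated correlation) were called down against untransfected cells. None of 20 and 12 members was called (2 lower and 0 adjusted over the list alone). The p53 targets (median 0.14, adjusted p = 0.044; adjusted p = 0.26 with an estimated correlation) were called up, and Cdkn1a and Plk2 were the 2 higher of 19 (2 adjusted over the list alone). Interferon response genes were also called up (median 0.14, adjusted p = 0.044; adjusted p = 0.26 with an estimated correlation), with none of 13 called over all genes or adjusted over the list alone. Fry did not call the stem cell, FGF and ERK feedback and interferon lists here (adjusted p = 0.16, 0.16 and 0.074). Without scrambled positive 2 the FGF and interferon lists were not called, nor the interferon list without scrambled positive 3 or untransfected 1, nor the p53 list without scrambled positive 1, scrambled positive 3, untransfected 2 or untransfected 3.

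Scrambled negative and untransfected cells were compared to ask whether cells of a transfected dish that lacked mCherry differed from untransfected cells. No gene was called by edgeR, with 257 genes at an unadjusted p under 0.05 and 7.1% of all tested genes without overlap, while DESeq2 called 1 gene and limma on TPM 0. With the replicate number as a block 0 genes were called, and 0 over the 9 control libraries alone. Hand1 (0.11, SE 0.12), Tfap2c (-0.03, SE 0.07), Eomes (-0.03, SE 0.13), Elf5 (-0.11, SE 0.10), Esrrb (0.14, SE 0.11) and Prl3d1 (-1.28, SE 0.75) had adjusted p of 0.94 to 0.97. Immediate early genes were called up in scrambled negative cells (median 0.14, adjusted p = 0.0027; adjusted p = 0.29 with an estimated correlation) and mitosis genes down (median -0.10, adjusted p = 0.036; adjusted p = 0.35 with an estimated correlation). None of 19 and 22 members was called over all genes or adjusted over the list alone, and fry called neither list (adjusted p = 0.31 for both). Without scrambled negative 1, scrambled negative 2 or untransfected 2 the mitosis list was not called.

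**Figure D4:**
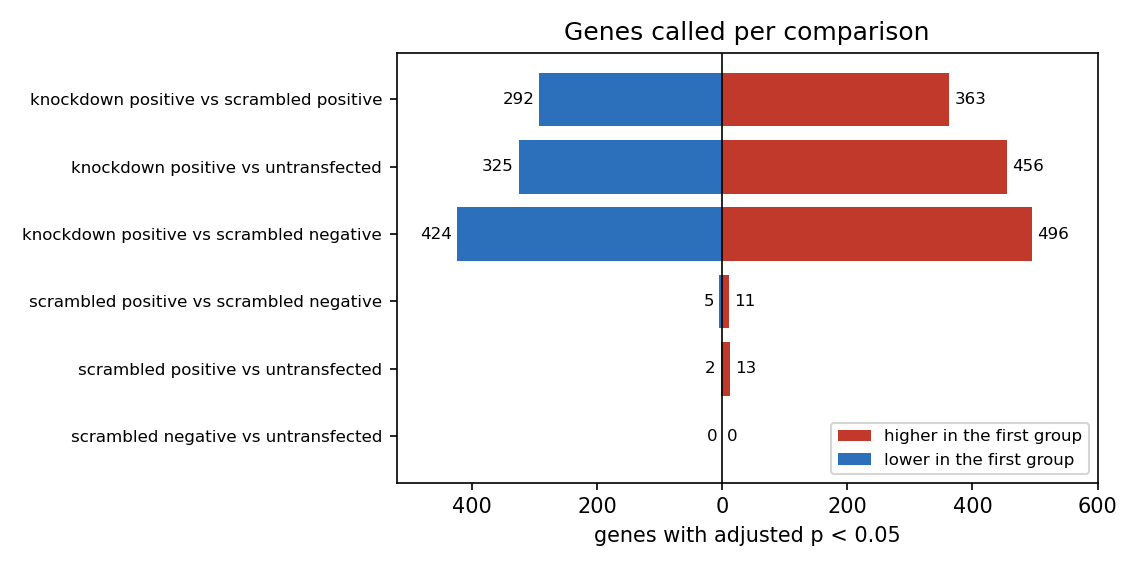
Number of genes with an adjusted p under 0.05 (horizontal axis) that were higher (right, red) or lower (left, blue) in the group named at the start of each of the 6 comparisons (vertical axis). Counts of higher and lower genes were 363 and 292, 456 and 325, and 496 and 424 for the knockdown contrasts, and 11 and 5, 13 and 2, and 0 and 0 between control groups.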

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

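Groups of 3 limit all counts, the sources hold no other Cdx2 shRNA label, and the replicate number is not known to pair libraries in any contrast. No called result among 191 named gene results and 126 list tests turned direction. Values near 0 that were not called did, such as Prl3d1 (0.43, from -0.65 to 0.85) and Eomes (-0.09, from -0.20 to 0.01) in knockdown against scrambled positive cells. Without any 1 library, 32 of 58 named calls of knockdown against scrambled positive cells stayed, 24 of 40 against untransfected, 28 of 42 against scrambled negative, 1 of 10 between scrambled groups and 0 of 9 for scrambled positive against untransfected cells. The Cdx2 log2 change of -1.11 stayed between -1.01 and -1.18. Why counts moved was not tested.

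Counts below are in the order knockdown against scrambled positive (655), untransfected (781) and scrambled negative cells (920), scrambled positive against scrambled negative (16) and untransfected (15), scrambled negative against untransfected (0), and all 3 knockdown contrasts (377). RLE size factors gave 629, 751, 890, 15, 15, 0 and 363; no filter 532, 669, 748, 15, 15, 0 and 316; and DESeq2 938, 1120, 1343, 171, 87, 1 and 526. Fits of only the 2 groups gave 263, 1125, 349, 0, 0 and 0. With a replicate block the counts were 877, 1075, 1299, 31, 38, 0 and 508; 7 of 12 libraries were closest to a library of another group with the same number, a hint from the data only. In the knockdown contrasts correlations of same-numbered libraries were -0.34, -0.09 and 0.54 (scrambled positive), -0.33, 0.06 and 0.24 (untransfected), and -0.42, 0.05 and 0.57 (scrambled negative). The replicate block changed no call of a named gene and ended 1 list call, BMP and TGF-beta feedback against untransfected cells.

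Leaving out 1 library gave 287 (knockdown 2) to 595 (scrambled positive 2), 352 (untransfected 3) to 475 (knockdown 1), 401 (knockdown 2) to 708 (scrambled negative 2), 2 (scrambled positive 3) to 13 (scrambled negative 2), 1 (scrambled positive 3) to 8 (scrambled positive 2), 0 to 0, and 171 (knockdown 2) to 437 (scrambled positive 2).

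Alternatives chosen after seeing the data gave the following. Without knockdown 1, scrambled positive 2 and scrambled negative 2 the counts were 1036, 1763, 1346, 23, 39, 0 and 703; with the GC and length correction 1653, 2107, 2230, 178, 106, 0 and 1017; with 1 surrogate variable 2728, 3143, 3791, 1331, 361, 2 and 1576; and by limma on TPM 423, 504, 624, 6, 3, 0 and 218. A replicate block over the 9 control libraries gave 121, 736 and 0, with 29.3% of the 736 higher. By limma on TPM the median log2 change of all genes was -0.102 for scrambled positive against negative and -0.135 against untransfected cells.

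Of named gene calls, limma on TPM ended 42, fits of 2 groups 55, no filter 12, RLE 4, leaving out the 3 libraries 6, the GC and length correction 2, and DESeq2 and the surrogate variable 0. Of 27 list calls, an estimated correlation left 0. The test fry gave 34 calls (9 ended, 16 added), the replicate block 26 (1 ended), the fit without the 3 libraries 25 (10 ended, 8 added), the GC and length correction 24 (7 ended, 4 added), and leaving out 1 library 22 to 33.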

Other observations

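The endothelial, YAP and TEAD target, placental family and histone lists were drawn up after the named genes of the main comparison had been seen and left those genes out. The fits without 3 libraries, with a GC and length correction, with 1 surrogate variable and on TPM were also chosen after the result was seen. After Cdh5, 13 measured genes of endothelial cells were followed. Against scrambled positive cells 5 rose and 0 fell (7 rose adjusted over the list alone). Kdr, the receptor of Vegfa, rose by 1.04 (SE 0.186, adjusted p = 0.0073) and Pecam1, an adhesion molecule of endothelial junctions, rose from 12.3 to 25 CPM (1.02, SE 0.129, adjusted p = 0.00101). Mcam, an adhesion receptor (0.73), Plvap, a component of fenestrae (0.57), and Flt4, a receptor of lymphatic growth factors (0.47), rose as well. Nos3 (0.74, adjusted p = 0.157), Eng (0.49, 0.174), Egfl7 (0.16, 0.82) and Erg (-0.60, 0.45) were not called. Against untransfected cells 3 rose (6 rose and 1 fell adjusted over the list alone) and against scrambled negative cells 2 (6 adjusted over the list alone). Kdr (adjusted p = 0.0533 and 0.0658) and Flt4 (0.22 and 0.221) were called in neither. The list was called up by camera against scrambled positive (median 0.47, adjusted p = 0.00019; 0.023 with an estimated correlation), untransfected (4.5e-05; 0.015) and scrambled negative cells (9e-04; 0.039). Camera did not call it between scrambled positive and the other control groups (adjusted p = 0.49 and 0.89). The test fry for changes in either direction did (0.0026 and 0.02). These p-values were adjusted over the 4 added lists only, so they cannot be compared with those of the 21 fixed lists. With an estimated correlation the unadjusted camera p against scrambled positive cells was 0.0059. The fixed epithelial list, at 0.0071, had an adjusted p of 0.13. Psg29, a pregnancy-specific glycoprotein gene, was the only called gene of 4 measured in the placental families against scrambled positive cells. It rose from 0.36 to 2.98 CPM (2.91, SE 0.458, adjusted p = 0.00363). Psg29 was not called against untransfected cells, where it stood at 1.17 CPM (1.335, adjusted p = 0.0709). Against scrambled negative cells, at 0.95 CPM, the rise was smaller (1.597, adjusted p = 0.0314). None of 16 YAP and TEAD targets was called (0 rose and 2 fell adjusted over the list alone; list adjusted p = 0.19), nor any of 44 histone genes (list adjusted p = 0.82).

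Genes that differed between scrambled positive cells and another control were followed into the knockdown contrasts, and those outside the naming rule were chosen after their values were seen. Of the 655 genes called between knockdown and scrambled positive cells 11 were of this kind. Nol4l was higher in knockdown than in scrambled positive cells (0.85) but not called against untransfected cells (0.07, adjusted p = 0.823), as were Mgat4b (0.79 and 0.18) and St3gal1 (0.91 and 0.34). Anxa8, an annexin, was lower against scrambled positive cells (-1.79) and not called against untransfected cells (0.77, adjusted p = 0.116), while it was higher in scrambled positive than in untransfected cells (2.56, adjusted p = 0.00197). Arhgef7 was called against both (1.3 and 0.60). Csf1r, a receptor of macrophages and trophoblast, rose in scrambled positive (1.98) and further in knockdown cells (3.03, both against untransfected).

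The median log2 change of 0.47 of the endothelial genes had an interval over genes of 0.01 to 0.73. This interval treats genes as independent and holds no spread between libraries. The list was also chosen after Cdh5 had been seen to rise in the same libraries. A rise of the list as a whole therefore stays open. Medians of the YAP and TEAD targets (0.11, interval -0.04 to 0.34) and histone genes (-0.04, interval -0.17 to 0.14) did not have the sign of Cyr61, Ctgf and Hist1h1c. These intervals also treat genes as independent, while estimated correlations between members were 0.35 and 0.27. The histone genes had a median level of 0.619 CPM, and their median change against scrambled negative cells was 0.25 (camera adjusted p = 0.20). Whether either list moved with those genes therefore stays open. Placental families (0.61, interval -0.20 to 2.91) cannot tell. A direct action of Cdx2, a later step of differentiation and an off-target effect of the shRNA cannot be told apart with these samples.

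Library 2 of both scrambled groups and of the untransfected cells stood apart within their groups, and the knockdown libraries were spread along the same component (20.8, -0.4 and -20.4). Removing trends with GC content and transcript length took away 83.5% of the variance along this component, so a difference in library preparation or RNA quality may lie behind it. Fewer counts as such are excluded as the cause, as 97% of the variance stayed after thinning to the smallest total. Fibroblast RNA is excluded as well, as Col1a1 and its relatives reached at most 0.25 CPM. Scrambled positive 2, scrambled negative 2 and untransfected 2 had the lowest totals of their groups (22.1, 27.8 and 25.8 M). Knockdown 1 also had the lowest total of its group (24.9 M). A preparation difference that also lowered the total therefore stays open. Most calls between knockdown and scrambled positive cells did not depend on the component that set these libraries apart. Of these calls, 95.4% stayed after the trends were removed. Without knockdown 1, scrambled positive 2 and scrambled negative 2, 574 of the 655 genes were still called. Without these libraries 100% kept most of their log2 change, a test that genes without overlap between the groups could hardly fail.

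Chance can be excluded for the count of genes called against all 3 controls, since 1 of 100 groupings, the real one, gave 377 and the highest other gave 0. It is not excluded for each single gene. The other groupings had at most 2 of the 3 knockdown libraries in the first group. The knockdown difference thus lay within their groups or among their controls. A difference in handling shared by the 3 knockdown libraries would also pass this test. For each comparison the 10 splits are too few for a share under 0.05. In the 5 comparisons with calls 1 of 10 splits, the real one, gave as many (655, 781, 920, 16 and 15) and the highest other gave 0. Scrambled negative against untransfected cells gave 0 calls in 10 of 10 splits. In the contrasts of scrambled positive with the other controls replicate numbers may pair libraries. There the 4 splits that part all 3 pairs also gave at most 0 besides the real one.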
